A study of Ogataea angusta with 8 samples.

How the data were processed

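Relative transcript levels were measured on 8 two-colour arrays of Hansenula polymorpha DL-1-L, listed under the organism name Ogataea angusta. Per the labels' protocols, total RNA was extracted with hot phenol and cleaned on a column, and 30 µg of each sample was copied into cDNA from an oligo dT primer and labelled with aminoallyl chemistry. Cultures were inoculated at an optical density of 0.3. Each array carried xylose and glucose RNA of 1 oxygen condition, with the dyes swapped between arrays. The labels name the arrays by the dye of the xylose RNA and a number (cy5-1, cy5-2, cy3-1, cy3-2). They do not say whether arrays came from separate cultures, or whether arrays of opposite dye share RNA extracts. The p-values therefore measure the spread between these arrays, which may be technical.

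The only file used is the deposited table of 1 log2 ratio per feature and array, made by the authors. Scanner, background correction, normalization, treatment of repeated spots and the log base are not given in the sources used here. The values are given to 2 decimals and each array's mean lies within 0.0013 of 0, as after centring or normalization of each array. The medians of microaerobic arrays cy5-1, cy5-2, cy3-1 and cy3-2 were -0.02, 0, -0.02 and -0.02, and those of the aerobic arrays, in the same order, -0.02, 0, -0.03 and -0.03. Base 2 is an assumption: the base does not change any test, but it sets every fold and every threshold in folds. Intensities were not analysed here, so dim or saturated spots could not be marked, and no depth or detection limit can be given. The number of arrays limits the precision.

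Of the 5838 rows, 1 has no identifier and no values, and 123 of the other 5837 have no value on any array. Another 359 features lack a value on some arrays, for reasons the sources used here do not state. Features with at least 2 values in each condition were tested, 5674 in all, and 40 with fewer values were left out. This minimum, and the use of the ratios without further centring, were settled once the data were seen. No identifier occurred more than once, and none matched any of the 5442 genes of the reference table for assembly ASM1920747v1. For this reason the 26 gene lists fixed beforehand could not be matched to any feature and were not tested, and no gene is named.

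The ratios were first checked for their direction. All pairs of arrays correlated above 0 in spite of the dye swap, and the mean over the swap had an SD across features of 0.34 (microaerobic) and 0.31 (aerobic), against 0.16 and 0.15 for the dye component, the deviation from that mean where the xylose RNA carried Cy5. With the signs of the arrays turned where the xylose RNA carried Cy3, limma called 0 and 2 features in the microaerobic and aerobic conditions. These counts follow from the positive correlations, since turning the signs moves a shared response into the spread. They do not measure dye bias. Dye bias of single features, in ratios left as Cy5 over Cy3, would also give positive correlations, so this check cannot settle the direction. The ratios were used as deposited, with no sign changed. The numerator is likely the xylose RNA, which is channel 1 of every array.

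Log2 ratios were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 fit over all 8 arrays with a coefficient per oxygen condition. Each coefficient was tested against 0, and their difference, aerobic minus microaerobic, was tested in the same fit. P-values were adjusted by Benjamini-Hochberg over the tested features, and an adjusted p under 0.05 was a call. A dye effect cancels in the mean of 2 arrays of each orientation but adds to the spread, so a dye term was tried as an alternative. That term was itself called for 212 features, with a median absolute size of 0.33 on the log2 scale. Of these, 78 had the higher ratio where the xylose RNA carried Cy5 and 134 the lower one. Overlap was tested per direction with Fisher's exact test.

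The tests of the 3 comparisons, most of the alternative settings and a naming rule were fixed before the data were examined, and choices made later are named where they are reported. With no gene names, the rule allows at most 2 identifiers that rose and 2 that fell. They are the features with the largest mean over both conditions in each direction, among those called and of 1 sign on all 8 arrays. Ranking on the mean of both conditions was settled after the data had been seen. Other features are described without an identifier.

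Whether dye and number pair the arrays of the 2 conditions was checked before the calls of any fit were compared. Deviations from the condition means correlated across features at 0.24, 0.21, 0.34 and 0.29 for the arrays cy5-1, cy5-2, cy3-1 and cy3-2, against 0.03 to 0.06 for arrays of the same dye and the other number. All 4 pairs lie above the bound of 0.1 set for pairing, so a fit with dye and number as a replicate block was added. The 4 values are not independent, since the deviations are taken from the mean of the same arrays. Within a dye the 2 numbers give 1 comparison, with r of 0.18 for Cy5 and 0.42 for Cy3. The pairing comes from the data and the titles, which name no shared day or slide. Within a condition, arrays of the same number and opposite dye did not deviate together (r of -0.04 and -0.02 between the differences of number 1 and number 2).

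The fit was tested on simulated ratios with the real spread and gaps, in 10 simulations with 200 changed features among 5674. For the microaerobic comparison it recovered 23.6%, 67.1% and 97.5% of changes of 0.3, 0.5 and 1 on the log2 scale, with 5.8 false calls on average. For the difference between conditions it recovered 3.55%, 34.8% and 86.5%, with 3.7 false calls. The simulated noise was independent between arrays, with no dye effect and no link between arrays of the same dye and number. Changes were placed in the microaerobic arrays only, and the 200 are fewer than the 1160 and 669 features called in the real conditions. Recovery and false calls on the real arrays may therefore differ. Alternatives varied the dye term, the blocks, averaging of same-number arrays, centring, scaling to an equal median absolute value, quantile normalization, missing values, the variance model, the spread filter and the thresholds, and left out each array in turn.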

Results

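The series measured relative transcript levels in the yeast Hansenula polymorpha (strain DL-1-L), a methylotrophic species that tolerates heat and can use xylose, a pentose sugar of plant biomass, as a carbon source. Total RNA of cells grown on xylose and of cells grown on glucose was labelled with a red (Cy5) and a green (Cy3) dye and hybridised together, so that each array gives the ratio of the sugars under 1 oxygen condition. Of the 8 arrays, 4 compared the sugars in microaerobic cultures and 4 in aerobic cultures. Both kinds of culture were grown at 37 °C, the microaerobic ones in 250 ml flasks holding 100 ml of medium and shaken at 100 rpm, the aerobic ones in 500 ml flasks holding 50 ml and shaken at 180 rpm. In each condition the xylose RNA carried Cy5 on 2 arrays and Cy3 on the other 2. No array compared aerobic with microaerobic RNA. The tested set was 5674 of the 5837 features, and the number of features with a value ranged from 5493 to 5677 per array. The features carry identifiers of the array design only. None of them was paired with a gene name in the tables used here, so the responses are described by number, size and direction, and 4 features are given in full by identifier.

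All 8 sets of ratios ran the same way, with a correlation above 0 for every pair of arrays. Between arrays of opposite dye orientation it was 0.52 to 0.60 across features in the microaerobic condition and 0.51 to 0.56 in the aerobic condition. Ratios left as Cy5 over Cy3 on every array, with dye bias of single features, could also correlate above 0. Such ratios could agree between the conditions too, a reading taken up below. Which RNA is the numerator is not stated. Xylose RNA was the first channel of every array and names every sample, so a positive ratio likely stands for a higher level on xylose, and "rose" and "fell" are used in that sense. Folds take the ratios to be on the log2 scale, a base that no source used here states.

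The first comparison asked which transcripts differ between xylose-grown and glucose-grown cells when oxygen is limited. In microaerobic cultures, 1160 of 5674 features (20.4%) changed, of which 554 rose and 606 fell on xylose. Which direction had more features depended on the setting, with 586 and 551 after median centring and 511 and 662 without features of high spread. Most changes were small. The median was 0.48 on the log2 scale among features that rose and -0.42 among those that fell, and 112 features changed by 2-fold or more. Of these 112, 77 had a positive ratio and 35 a negative one, and of the 11 features that changed by 4-fold or more, 7 were positive and 4 negative. These are rises and falls on xylose in that order, and the reverse if glucose is the numerator. Of the 1132 called features with a value on all 4 microaerobic arrays, 1084 had the same sign on all 4. Features were called with limma, at an adjusted p under 0.05, in 1 fit over all 8 arrays that pools their spread. The median standard error of a mean ratio was 0.097, and the smallest called change was 0.22 on the log2 scale. The count was 710 without microaerobic array cy3-1, 685 without microaerobic array cy3-2, 1490 with a dye term and 1886 with label number as a random block.

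Feature KH-1683 rose on xylose in microaerobic cells by 2.76 ± 1.09 on the log2 scale (SD, n = 4), or 6.76-fold (limma adjusted p = 7.3e-05). Its 4 values ran from 1.66 to 3.83 and split by dye, with a mean of 1.82 where the xylose RNA carried Cy5 and of 3.69 where it carried Cy3. Feature KH-0088 rose by 2.69 ± 0.40 (SD, n = 4), or 6.44-fold (limma adjusted p = 7.8e-07). Its ratio was below that of KH-1683 over the 4 arrays, but above it after quantile normalization (2.94 against 2.69), without microaerobic array cy3-1 (2.65 against 2.40) and without microaerobic array cy3-2 (2.63 against 2.49). Feature KH-2157 had a log2 ratio of -3.29 ± 0.24 (SD, n = 4), a level 9.78-fold lower on xylose (limma adjusted p = 1.0e-07). Feature KH-1711 had a log2 ratio of -2.29 ± 0.34 (SD, n = 4), or 4.90-fold lower (limma adjusted p = 7.8e-07). The values of KH-2157 and KH-1711 also split by dye, less widely than those of KH-1683. Their means were -3.495 and -2.025 where the xylose RNA carried Cy5, and -3.085 and -2.56 where it carried Cy3.

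The second comparison asked the same of well-aerated cells. In aerobic cultures, 669 of 5674 features (11.8%) changed, of which 345 rose and 324 fell on xylose. This split also depended on the setting, with 384 and 272 after median centring and 353 and 396 without features of high spread. The median was 0.55 on the log2 scale among features that rose and -0.45 among those that fell. Of the 101 features that changed by 2-fold or more, 75 had a positive ratio and 26 a negative one, and of the 13 that changed by 4-fold or more, 12 were positive and 1 negative, which again would read as falls and rises with glucose as the numerator. Of the 657 called features with a value on all 4 aerobic arrays, 637 had the same sign on all 4. The median standard error was again 0.097. The count was 357 without aerobic array cy3-1, 355 without aerobic array cy3-2, 969 with a dye term, 1270 with label number as a random block and 1093 with same-number arrays averaged.

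In aerobic cells KH-1683 rose by 3.62 ± 0.56 on the log2 scale (SD, n = 4), or 12.3-fold (limma adjusted p = 1.4e-05). Feature KH-0088 rose by 2.94 ± 0.45 (SD, n = 4), or 7.69-fold (limma adjusted p = 1.1e-06). Feature KH-2157 had a log2 ratio of -1.93 ± 0.45 (SD, n = 4), or 3.80-fold lower on xylose (limma adjusted p = 6.5e-06). Feature KH-1711 had a log2 ratio of -1.85 ± 0.31 (SD, n = 4), or 3.61-fold lower (limma adjusted p = 4.9e-06). The aerobic values of KH-2157 and KH-1711 split by dye as well, and those of KH-1683 narrowly. KH-1683, KH-0088, KH-2157 and KH-1711 are among 395 features that were called in both conditions and kept 1 sign on all 8 arrays, of which 215 rose and 180 fell.

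**Figure D1:**
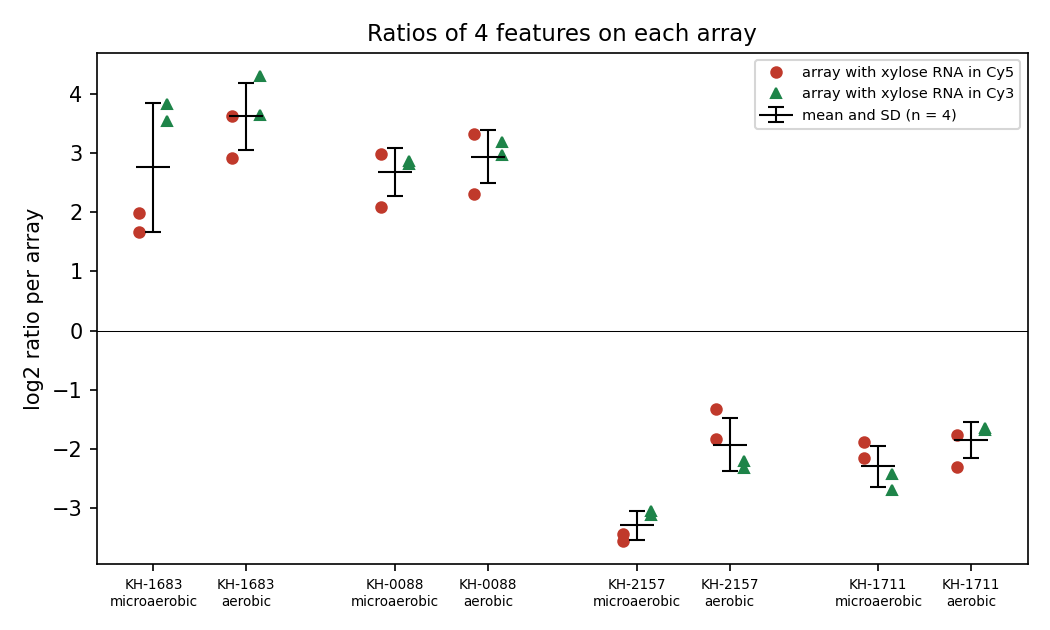
Log2 ratios (vertical axis) of features KH-1683, KH-0088, KH-2157 and KH-1711 on each of the 4 microaerobic and 4 aerobic arrays (horizontal axis). Circles are arrays with xylose RNA in Cy5 and triangles arrays with xylose RNA in Cy3, and bars give the mean and SD (n = 4). The first 2 features lie above 0 and the other 2 below 0 on every array. The values of KH-1683, KH-2157 and KH-1711 part by dye in both conditions, and those of KH-0088 in neither. The widest parting of the means is that of KH-1683 in microaerobic cells, while its aerobic values part only narrowly.

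The third comparison asked whether the response to xylose depends on the oxygen supply. The lists of called features shared more members than independent lists of their lengths would. Of the features that rose, 236 did so in both conditions, where lists of these lengths would share 33.7 by chance (odds ratio 34.1, 95% interval 26.3 to 44.4, Fisher's exact test, two-sided p = 1.8e-173). Of those that fell, 193 did so in both, against 34.6 by chance (odds ratio 17.6, 95% interval 13.7 to 22.6, Fisher's exact test, two-sided p = 1.3e-112). Features are not independent replicates, so these p-values describe the lists only. The chance counts take the lists as independent, but both come from 1 fit that pools the spread of a feature over all arrays. Fits on each condition's arrays alone shared 383 features in the same direction. In all, 429 features were called in both conditions in the same direction. This count was 259 without aerobic array cy3-1, 256 without aerobic array cy3-2, 634 with a dye term, 802 with label number as a random block and 711 with same-number arrays averaged. Among the large changes, 59 features changed by 2-fold or more in both conditions, 46 of them positive in both, 13 negative in both and none of opposite signs. With glucose as the numerator these would be 46 falls and 13 rises.

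Most features called in either condition had the same sign in the other. Of the 554 features that rose in microaerobic cells, 477 (86.1%) had a positive mean ratio in aerobic cells, with a median of 0.29 against 0.48 in the microaerobic arrays on which they were chosen. Of the 606 that fell, 558 (92.1%) had a negative mean ratio in aerobic cells. Of the features chosen on the aerobic arrays, 331 of the 345 that rose and 288 of the 324 that fell had the same sign in microaerobic cells. Over the 5355 features with a value on all arrays, the mean ratios of the conditions correlated with Pearson's r = 0.72 and Spearman's rho = 0.60. Features are not independent replicates here either. From arrays of different numbers in their titles, r was 0.62 and 0.65, and from arrays of the same number 0.71 and 0.66. These values rest on fewer arrays than the r over all arrays, so only they compare with each other.

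A direct test of the difference between conditions called 58 features with limma, a count that depends on the model. It was 173 with a dye term, 129 with number as a fixed block and a dye term, 159 without features of high spread, 278 with label number as a random block and 352 with same-number arrays averaged. The aerobic ratio was the higher one for 19 of the 58 and the lower one for 39, but the split was nearer to even under some other settings, with 70 and 103 with a dye term and 10 and 11 without both cy5-2 arrays. The response had the same sign in both conditions and was larger in microaerobic cells for 24 of the 58, was larger in aerobic cells for 5, and had opposite signs for 29. Among those 29, 11 features were called in both conditions with opposite signs, and no other feature was so called. Arrays whose titles give the same dye and number deviated together in the 2 conditions, and with dye and number as a block the test called 101 features, 54 of them among the 58. The count of 58 fell to 30 without microaerobic array cy5-1, to 32 without microaerobic array cy5-2, to 36 without aerobic array cy3-2, and to 21 without the cy5-2 arrays of both conditions, an alternative chosen after seeing the data.

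Over all 8 arrays as deposited, the largest contrast of opposite signs was that of a feature with a log2 ratio of 0.98 ± 0.27 in microaerobic cells, positive on 4 of 4 arrays, and of -1.03 ± 0.30 in aerobic cells, negative on 4 of 4 (SD, n = 4 each). Its difference, aerobic minus microaerobic, was -2.01 ± 0.17 (SE, limma adjusted p = 2.1e-04). The largest difference in the other direction was that of a feature at 0.35 ± 0.33 in microaerobic and 2.28 ± 0.29 in aerobic cells (SD, n = 4 each), positive on 3 of 4 and 4 of 4 arrays, with a difference of 1.92 ± 0.18 (SE, limma adjusted p = 2.6e-04). These 2 features were chosen after their values were seen. The fall of KH-2157 was the deeper one in microaerobic cells, by 1.36 ± 0.20 on the log2 scale (SE, limma adjusted p = 0.0059), but after quantile normalization the difference was 0.66 and did not pass (limma adjusted p = 0.38, against 2.6e-05 to 0.38 over 19 alternatives). The size of this difference depended on the dye. Where the xylose RNA carried Cy5, the means of KH-2157 were -3.495 in microaerobic and -1.585 in aerobic cells. Where it carried Cy3, they lay closer together, at -3.085 and -2.27. For KH-1683, KH-0088 and KH-1711 the difference did not pass the test (limma adjusted p of 0.48, 0.73 and 0.37), but with same-number arrays averaged those of KH-1683 (limma adjusted p = 0.0011) and KH-1711 (limma adjusted p = 0.048) did.

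A call in 1 condition only does not show that the conditions differ. Of the 720 features called only in the microaerobic comparison, 20 passed the test of the difference, as did 15 of the 229 called only in the aerobic comparison. The SD of the log2 ratios over features holds noise and dye effects besides the response on an array, so it does not compare the response alone. This SD was 0.39 ± 0.03 in the microaerobic and 0.37 ± 0.03 in the aerobic arrays (mean ± SD, n = 4 each, exact permutation test, two-sided p = 0.23). It was higher in the microaerobic array in 4 of 4 pairs of arrays with the same dye and number, for which an exact test cannot give a two-sided p under 0.125.

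**Figure D2:**
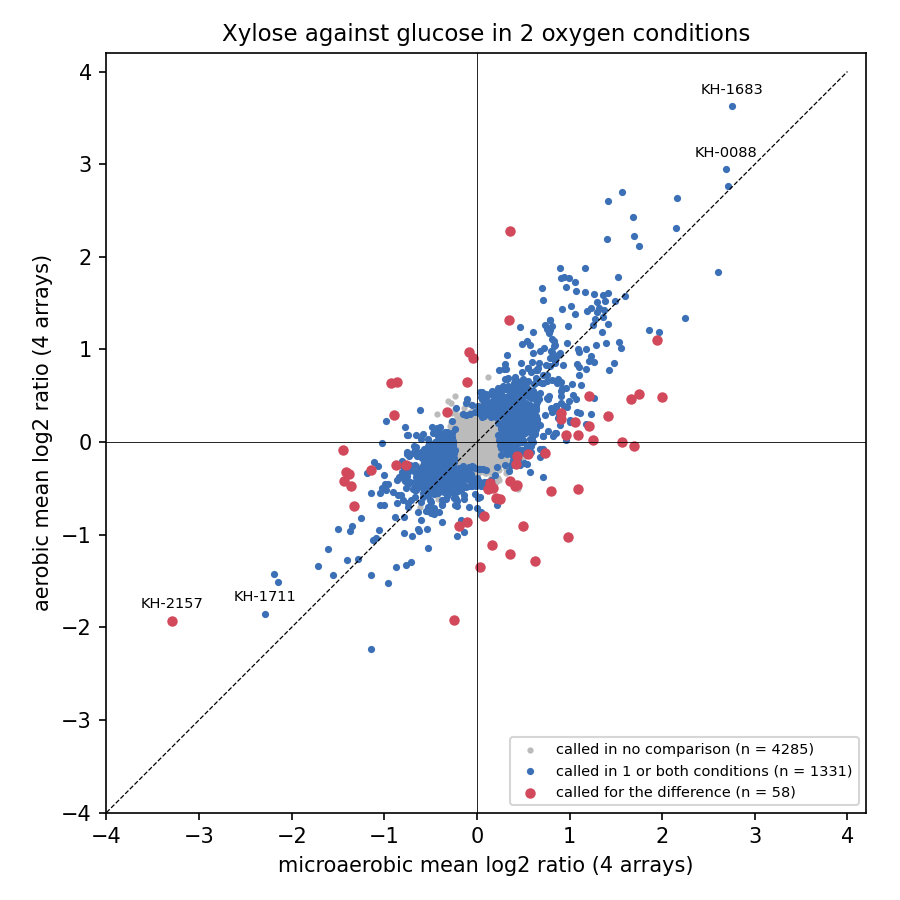
Mean log2 ratio of each of the 5674 tested features in microaerobic cells (horizontal axis, 4 arrays) and in aerobic cells (vertical axis, 4 arrays), with positive values likely standing for a higher level on xylose. Red points are the 58 features called for the difference between conditions, blue points those called in 1 or both conditions only, and grey points the rest, and the dashed line marks equal ratios. Most called points lie in the quadrants of equal sign, and KH-2157 lies above the dashed line.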

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

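The count of splits was set out before its result was seen. The tests of shared array effects, of both dye explanations (for the difference, the latest of 3 tried), of the orientation and of the scale factor, the splits fitted with a dye term and the splits limited to those that part 4 pairs were chosen after related values had been seen.

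The test of the difference between conditions called 58 features, 11 of them called in both conditions with opposite signs, and the count fell to 30 without microaerobic array cy5-1, to 32 without microaerobic array cy5-2, to 36 without aerobic array cy3-2 and to 21 without both cy5-2 arrays. Of the 35 splits of the 8 arrays into 4 and 4, 2 called as many, so chance is not excluded by this count; the other was the split by dye, with 83 calls, the highest of the other splits. Among the 8 splits that part all 4 pairs of arrays the highest other count was 1, and with a dye term the real split called 173 features and the highest of the others 3, with 1 of 34 splits calling as many. Additive effects of the dye, or of arrays that share dye and number, cancel in the difference where all 8 arrays have a value, if they are equal in both conditions. All 8 values were present for 98.3% of the called features (57 of 58). This share decides nothing, since it was 94.4% among tested features. For effects equal in both conditions, the balance of the design argues against them as the source for these 57 features. Effects that differ between conditions are not argued against, and deviations of paired arrays correlated at 0.21 to 0.34. Fits with such terms, which called 173 (58 of them among the 58) and 101, do not test this. Earlier tests of the dye asked for 1 sign in both orientations, which all 58 had, a share partly set by how they were chosen, and for the sign of the 58 features with the largest difference in 1 orientation only, of which 87.9% (chosen in Cy5) and 74.1% (chosen in Cy3) had the same sign in the other; oxygen supply, flask, volume and shaking, which changed together, stay open and untested.

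The ratios had been taken as oriented because they kept 1 sign across the dye swap. Were they Cy5 over Cy3 on every array instead, the mean over the swap would be dye bias. A bias equal in both conditions would cancel in the difference, yet 28 features were called for the difference at 2-fold or more. This argues against an equal bias only, and the count shares the limits given for the difference. All called features had 1 sign in both orientations, so asking for that sign removed none and adds nothing. A dye bias that differs between conditions is not argued against. Which sugar is the numerator stays open, since the values are symmetric in that choice, and no biological explanation was tested.

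Among called features with a value on all 8 arrays, those with positive ratios, which rose if xylose is the numerator and fell if glucose is, had larger ratios where the xylose RNA carried Cy3. Their mean ratio was 1.23 times that in Cy5 arrays in microaerobic cells (95% bootstrap interval over features 1.16 to 1.31) and 1.37 times in aerobic cells (1.29 to 1.45), while the factor of features with negative ratios was 1.08 and 1.04. A single scale factor per orientation is argued against, since the factors of positive and negative features lay 0.154 or more apart in both conditions. Dye bias of single features may contribute, but not to positive ratios alone: among features with a value on all 8 arrays, the dye component correlated between conditions at r = 0.384 across the 642 called with a positive ratio in either and at 0.274 across all 5355, and, although arrays of the same dye and number deviated together, the covariance over the 642 between arrays of different numbers was 0.848 times that over all arrays. Signal near background in the channel of the denominator stays open, as no intensities were used, and no biological explanation was tested.

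For single arrays and features, 16 sets of 4 values were screened for a value far from the others, which chance gives in about 5% of sets. Microaerobic array cy5-2 stood apart with 344 features without a value, against 167 to 186 on the other microaerobic arrays, and with a median ratio of 0 against -0.02 on each of them, in values given to 2 decimals. Aerobic array cy5-2 leaned the same way, with 273 against 160 to 191 and a median of 0 against -0.02 to -0.03, but did not pass the screen. The difference of KH-2157 between conditions, 1.36 on the log2 scale, passed its test but not after quantile normalization (0.66). It was wider between arrays with xylose RNA in Cy5 than between those with xylose RNA in Cy3.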

How the results depend on the processing

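The block of dye and number, leaving out both cy5-2 arrays, and the shared count under settings other than the dye term and the stricter threshold were chosen after seeing the data. All 160 values of the 4 identified features in the separate conditions kept their direction and their side of the threshold under the alternatives run, and 73 of 76 values of their difference kept their side, 1 of them with its sign turned (KH-0088, not called, from 0.26 to -0.12 after quantile normalization). The others were KH-2157 after quantile normalization (0.66 on the log2 scale, adjusted p = 0.38, range over alternatives 2.6e-05 to 0.38), and, with same-number arrays averaged, KH-1683 (adjusted p = 0.0011, range 0.0011 to 0.82) and KH-1711 (adjusted p = 0.048, range 0.048 to 0.74). Counts moved more. In the order microaerobic, aerobic, difference and shared in the same direction, they were 1160, 669, 58 and 429 as reported. By construction, an adjusted p under 0.01 gave 568, 325, 25 and 190, and a 2-fold minimum gave 112, 101, 28 and 59. A random replicate block of label number within condition, with an estimated correlation of -0.33, gave 1886, 1270, 278 and 802, and averaging same-number arrays gave 1627, 1093, 352 and 711. The dye term gave 1490, 969, 173 and 634. For the difference, a fixed replicate block of number with the dye term gave 129, the replicate block of dye and number 101, removing features of high spread 159 (37 of them among the 58), and leaving out both cy5-2 arrays 21. The cause of these shifts was not tested. By design, though, each label-number block and each same-number average held 1 array of each dye. A dye effect therefore cancels in such an average and pushes the correlation within such a block below 0. The block of dye and number moved no other count by over 1.5 times and changed no call of the 4 features. Leaving out single arrays gave 685 to 1193, 355 to 683, 30 to 50 and 256 to 423, with fewer arrays and an uneven dye balance. Median centring, scaling, quantile normalization, complete features, the trended and robust variance model and separate fits per condition left every count they gave within 1.5 times. Choosing 1 feature per gene was not run, since no identifier repeats, nor were the gene lists. Signal over background could not be used as a limit, since no intensities were used.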

Other observations

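The tests of identifier order and of empty cells, and the covariances by array number, were chosen after related values had been seen.

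Among the 236 features that rose in both conditions, the median ratio was 0.64 in microaerobic and 0.64 in aerobic cells, and 89 of them rose further in microaerobic cells. Among the 193 that fell in both, the median was -0.54 in microaerobic and -0.45 in aerobic cells, and 124 of them fell further in microaerobic cells. The contrast between these directions was not tested.

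The covariance of the mean ratios of the conditions across features was 0.0742 over all arrays. It was 0.0678 and 0.0750 between arrays of different numbers, and 0.0833 and 0.0707 between arrays of the same number. Among the 4015 features called in neither condition and measured on all arrays, the means correlated at r = 0.43, across features, to which effects common to paired arrays may contribute.

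Identifiers may follow array position or genome order, which a regional trend in the mean response over the arrays could show. No such trend was found. The correlation of the mean response between features with neighbouring numbers was -0.0011, at the 48.4th percentile of 10000 random orders. A mean over arrays can hide a trend on a single array. Trends along the identifiers on single arrays were not tested. Runs of neighbouring identifiers with ratios of 1 sign did occur, such as a long run of positive ratios on aerobic array cy5-1, whose median was -0.02. Gaps on the cy5-2 arrays also lay close together in places. Identifiers may therefore follow position, and position effects on single arrays stay open.

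Empty cells on the cy5-2 arrays of the 2 conditions fell on the same features more often than independent gaps would. Of 5533 features with a value on the other 6 arrays, 145 lacked one on microaerobic array cy5-2 and 67 on aerobic array cy5-2, and 34 lacked both, which is 19.4 times the 1.76 expected of independent gaps (Fisher's exact test, two-sided p = 2.0e-37). Whether the same recurs for other pairs of arrays was not tested. A shared print or scan, or features that are dim in general, are candidate explanations that these values do not separate.

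A further 40 features had values but too few to test. Of their 116 values, 33 (28.4%) were at 2-fold or more, against 2.44% of the values of tested features, and 24 of the 33 lay on microaerobic arrays, which held 63 of the 116.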
